A study of Mus musculus with 4 samples.

How the data were processed

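Total RNA of whole blood was isolated with the miRNeasy kit, made into small RNA libraries and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The deposited files, 1 per library, list loci with their count of mature reads, which are whole numbers and not normalized. Per the submitters' processing notes, the tools were Bowtie 0.12.2 and DESeq, with the mm10 build; the role of each tool, the caller of the predicted loci and the miRNA annotation release are not given in the sources used here.

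Each library's list was read as deposited. The lists held 954, 693, 637 and 583 rows for control 1, control 2, cadmium 1 and cadmium 2, with totals of 43666624, 30277884, 17064897 and 18575659. An unnamed row in cadmium 1 that held the column total was left out. The lowest count listed was 5, so a locus missing from a list is not a measured 0. A name and its star form repeated the same locus and count and were merged. Loci with the same mature sequence each count the same reads (95 of the annotated loci), and reads of near-identical copies could not be separated. The counted window was set per library: of 374 annotated loci, 289 were listed in all 4 libraries, 12 of these were counted on different hairpin arms and 41 on the same arm with shifted ends. In control 2 the sequence column was out of step with its rows (162 of 693 lengths match), so its sequences were not used. Of 365 mature sequences checked against hairpin transcripts of the GENCODE release for this build, 365 lay at the listed position; host genes, exons and introns come from that annotation. Coordinates are 1-based.

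Groups follow the labels. The main test was edgeR 4.0.16 (quasi-likelihood fit and F test, TMM normalization, filterByExpr, two-sided, Benjamini-Hochberg, threshold 0.05) in R 4.3.3, with group as the only term and 2 residual degrees of freedom. It ran on annotated loci listed in all 4 libraries on the same arm, 277 loci, of which filterByExpr removed 1. That restriction was set after the lists' structure was seen and before any test was run. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are TMM-normalized. TMM factors were 0.892, 0.912, 1.13 and 1.09. Depth is higher in controls, and the counts of most named loci are large enough that spread between libraries limits the precision more than counting error. Pearson correlations of log2 CPM across loci were 0.992 for the control pair and 0.998 for the cadmium pair. Chi-square per degree of freedom was 1023 and 60.8, so neither pair is 1 library listed again.

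Test, lists, naming rule and most alternatives were fixed before the data were examined. Named loci are the 10 of highest mean CPM, the up to 10 largest rises and 10 largest falls past the threshold with a mean CPM of at least 10 and no overlap between groups, the 2 most abundant members of each list, and miR-210, miR-122, miR-21 and miR-34a where tested. The 13 lists are erythroid, myeloid, platelet, lymphocyte, liver, kidney and epithelium, muscle, neural, let-7 family, miR-17-92 clusters, inflammation, p53 and hypoxia, and Dlk1-Dio3 cluster; 11 had at least 3 tested loci. They were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry, which asks whether a list's members move one way on balance and makes no comparison with other loci. Some loci are in more than 1 list.

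The test was checked on 20 simulated data sets of 276 loci with the real means and depths. The simulated spread followed the trend with abundance and was the same in both groups, though the real control libraries lay further apart than the cadmium ones. The rates hold for that simpler case. For cadmium against control the test called 19.1% of loci changed 1.5-fold, 61.6% of those changed 2-fold, 98.4% of those changed 4-fold and 0.329% of unchanged loci. A 2-fold move of the miR-17-92 list was called in 20 of 20 data sets with the preset correlation, in 2 with an estimated correlation and in 10 with fry. Each locus was drawn independently, copies included, while the real list had an estimated correlation of 0.13. These counts therefore do not show which setting is right for the real list.

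Alternatives were DESeq2 size factors, total counts, upper quartile, totals without dominant loci, no filter, a mean CPM of at least 10, DESeq2 1.42.0, edgeR's exact test, limma voom, the replicate number as a block, each library left out, and counts summed over arms and copies. Added after seeing the data were only loci with identical windows, 1 locus per mature sequence, unlisted loci as 0 or as 4 reads, predicted loci included, and counts thinned to the shallowest library. For shares of the counts each mature sequence was counted once, with 95% Wilson intervals that cover counting error only. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Names absent from these lists, such as miR-451 and miR-223, are not analysed here.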

Results

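Small RNA of whole blood was sequenced in 180-day-old Balb/c mice, an inbred albino laboratory strain. The control group had 2 libraries and the group given cadmium in its drinking water had 2. The dose and duration of exposure are not given in the sources used here. Counts of annotated microRNA (miRNA) loci summed to 35244119 and 24622926 in controls 1 and 2, and to 14383852 and 15565712 in cadmium libraries 1 and 2. The labels do not say whether the libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be technical. The comparison, cadmium against control, asks which blood miRNAs differ with cadmium, a toxic metal that accumulates in kidney and liver.

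Cadmium blood had less miR-486, the most abundant of the miRNAs analysed here and one enriched in red blood cells. It had more miR-18a, of the proliferation-linked miR-17-92 cluster, and more miR-326. miR-486 was 1.51-fold lower, with a log2 fold change of -0.60 ± 0.07 (SE, 2 libraries per group), while miR-18a was 4.47-fold higher (2.16 ± 0.26) and miR-326 4.55-fold higher (2.18 ± 0.24). The lymphocyte list fell and the miR-17-92 list rose in the camera test with its preset correlation. Neither passed with an estimated correlation (adjusted p = 0.666 for both), and with fry only the lymphocyte list did. Of 276 tested loci, 40 changed at an edgeR adjusted p under 0.05, of which 22 were higher and 18 lower with cadmium, and at an unadjusted p under 0.05 there were 79.

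Several loci encode the same mature sequence and count the same reads, so the 40 loci hold 35 distinct sequences, 19 higher and 16 lower. All 40 had no overlap between the groups, as did 193 of the 276 loci (chance gives 33.3% per locus with 2 against 2). All loci come from the same 4 libraries, so any difference between the pairs can separate many loci at once. The comparison with 33.3% is therefore no test of cadmium. The balance of rises and falls depended on scaling: 21 rose and 27 fell with DESeq2 size factors, 57 and 8 with total counts alone, 48 and 9 with the upper quartile, and 38 and 14 with totals that leave out the loci holding over 10% of the counts. The number of calls rested on the close pair of cadmium libraries. It was 8 and 9 without cadmium 1 and cadmium 2, and 105 and 122 without control 1 and control 2. Loci called in each of these 4 reduced fits were miR-486, its copy miR-3107, miR-326, miR-18a and miR-592, with miR-205 and miR-491, the last 2 outside the naming rule and singled out after their values were seen. The other 33 of the 40 lost their call without cadmium 1.

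miR-486 (chromosome 8, 23142587 to 23142608, plus strand, mm10) lies in an intron of Ank1, the gene of erythrocyte ankyrin. Its level was 253127 ± 11341 CPM in controls and 167228 ± 8297 CPM with cadmium (SD, n = 2 each; edgeR adjusted p = 0.00204), and the call was lost with upper quartile scaling (-0.35, adjusted p = 0.137). Its mature sequence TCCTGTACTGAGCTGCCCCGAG is also listed on the opposite strand as miR-3107, and both carry the same reads. With each mature sequence counted once, miR-486 held 38.3% and 36.3% of the counts in controls 1 and 2, and 29.4% and 30.7% in cadmium libraries 1 and 2 (the widest 95% Wilson interval, of cadmium 1, was 29.3% to 29.4% and covers counting error only). With every listed locus in the total, so that copies count more than once, the mean shares were 22.8% and 18.5%. Other very abundant miRNAs stood close to their control level: miR-16-1 and miR-16-2, which carry the same reads, had log2 fold changes of -0.04 ± 0.07, miR-22 had -0.10 ± 0.08, and miR-92a-1 and miR-92a-2 had -0.05 ± 0.14 and -0.08 ± 0.14. These small values turn positive with total counts, where the miR-16 loci pass the threshold at 0.26. miR-30a, miR-30e and miR-186, also among the 10 most abundant, fell by 0.66 ± 0.09, 0.41 ± 0.11 and 0.78 ± 0.12 on the log2 scale. The call of miR-30e was lost in 14 of 21 alternatives, among them total counts and the upper quartile. miR-30e and miR-186 lie in introns of Nfyc and Zranb2.

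Among higher miRNAs, miR-18a (chromosome 14, 115043867 to 115043889, plus strand) lies in an exon of the noncoding host transcript Mir17hg and rose from 202 ± 74.2 to 902 ± 27.8 CPM (edgeR adjusted p = 0.00204). miR-326 (chromosome 7, 99552328 to 99552347, plus strand), in an intron of Arrb1, the gene of beta-arrestin 1, rose from 24.2 ± 4.29 to 110 ± 11.2 CPM. miR-15b, in an intron of Smc4 beside miR-16-2, rose from 1436 ± 144 to 3066 ± 84.8 CPM, a log2 fold change of 1.09 ± 0.13. miR-324, miR-331, miR-700 and miR-345 rose by 1.60 ± 0.24, 1.38 ± 0.21, 1.37 ± 0.24 and 1.13 ± 0.21 on the log2 scale. miR-24, counted at miR-24-1 and miR-24-2 with the same reads, rose by 1.10 ± 0.20, and miR-195a, of the miR-15 and miR-16 seed family, by 1.06 ± 0.23.

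Among lower miRNAs, miR-592 (chromosome 6, 27936712 to 27936732, minus strand), in an annotated exon of the glutamate receptor gene Grm8, had the largest fall of the named loci, from 18.0 ± 1.14 to 2.22 ± 0.802 CPM, a log2 fold change of -3.02 ± 0.30 (edgeR adjusted p = 0.00204). miR-322, miR-31, miR-27b and miR-10b fell by 1.15 ± 0.27, 1.06 ± 0.23, 0.78 ± 0.14 and 0.72 ± 0.16. miR-10b lies in introns of Hoxd3 and Hoxd4. miR-322 dropped from 425 ± 166 to 192 ± 13.9 CPM, so its 2 controls were far apart, as were those of miR-18a for their level.

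**Figure D1:**
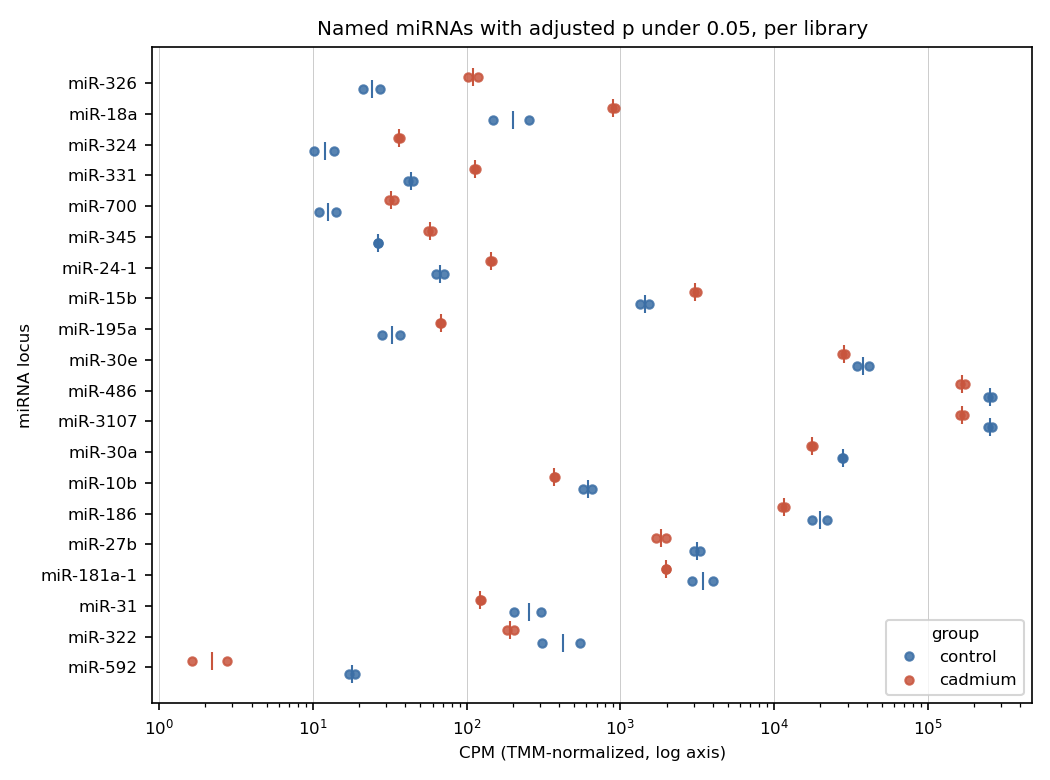
TMM-normalized CPM (log axis) of each named miRNA with an edgeR adjusted p under 0.05, sorted by log2 fold change; each point is 1 library, blue for control and red for cadmium, and each vertical tick is the mean of a group of 2. miR-18a stands at 202 CPM in controls and 902 CPM with cadmium, and miR-592 at 18.0 and 2.22 CPM; copies with the same reads are drawn once, except miR-3107 beside miR-486.

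Of the 10 tested lymphocyte loci, 2 fell and 0 rose over all loci tested (6 fell with DESeq2 size factors and 0 with total counts), and 6 fell and 0 rose adjusted over the list alone. Those 6 are both copies of miR-181a and of miR-181b, with miR-181c and miR-150, and copies carry the same reads. The 2 that fell over all loci, miR-181a-1 and miR-181a-2, carry the same reads of miR-181a, which is known from lymphocyte development, at -0.81 ± 0.16 (edgeR adjusted p = 0.0133, and 0.0550 with total counts). miR-150, a miRNA of mature lymphocytes, had -0.55 ± 0.18 (edgeR adjusted p = 0.0741). The list as a whole fell, with a median of -0.52 and a camera adjusted p = 0.00912. Its adjusted p = 0.666 with an estimated correlation, and its fry adjusted p = 0.0450. Of 5 myeloid loci, 2 rose over all loci and 3 rose adjusted over the list alone. The 2 were the miR-24 copies, which carry the same reads, and miR-23a joined them over the list alone. miR-142, found across blood cell lineages, had -0.07 ± 0.12 and miR-27a 0.09 ± 0.20. The list had a median of 1.10 (camera adjusted p = 0.140, fry adjusted p = 0.0486), which is the miR-24 value with both copies counted. With each sequence counted once the list mean was 0.61, and 0.37 without miR-23a.

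Of 10 erythroid loci, 2 fell over all loci, miR-486 and miR-144 (-0.58 ± 0.15, edgeR adjusted p = 0.0359), a miRNA of red cell precursors. Adjusted over the list alone, 1 rose, miR-183 at 0.85 ± 0.24, and 2 fell, and the list did not move as a whole (median -0.04, camera adjusted p = 0.771). Erythroid miRNAs held 63.2% ± 2.26 of the counts in controls and 59.9% ± 0.649 with cadmium (SD, n = 2 each). The list also names miR-451, which is not analysed here, so it is in neither the list test nor these shares. With every listed locus in the total the order turned, at 52.3% and 53.2%. In that count miR-3107 adds the reads of miR-486 to the total but not to the erythroid part, while both miR-16 copies add to each. The turned order therefore comes with unequal counting of copies and is no measure of red cell RNA. Without miR-486, the shares were 41.3% ± 2.25 and 42.6% ± 0.130. The exact two-sided permutation test of 2 against 2 cannot give a p under 0.333, and no other test of these shares was run. The 4 platelet loci had a median of -0.15 (camera adjusted p = 0.771), with 0 changed; miR-126a, of platelets and endothelium, stood at -0.15 ± 0.20 and miR-199a-1 at -0.15 ± 0.27.

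The miR-17-92 list takes in the miR-17-92 cluster and its paralogs miR-106a-363 and miR-106b-25. Of its 13 tested loci, 3 rose and 0 fell over all loci, and 7 rose and 0 fell adjusted over the list alone. The 7 include both copies of miR-19b, which carry the same reads. Over all loci 2 rose with DESeq2 size factors, 9 with total counts, 8 with the upper quartile and 5 without dominant loci. The 3 of the main test were miR-18a, miR-106a (1.20 ± 0.22) and miR-20b (0.86 ± 0.24, edgeR adjusted p = 0.0486, and 0.0732 with DESeq2 size factors). The list rose as a whole (median 0.47, camera adjusted p = 0.0152). Its adjusted p = 0.666 with an estimated correlation, its fry adjusted p = 0.149, and the call was lost without control 1 (adjusted p = 0.0703), with a mean CPM of at least 10 and with unlisted loci as 4 reads. Within the miR-17-92 cluster itself, miR-18a stood apart: miR-17 had 0.22 ± 0.13, miR-19a -0.16 ± 0.33, miR-20a 0.47 ± 0.15, miR-19b-1 0.79 ± 0.28 and miR-92a-1 -0.05 ± 0.14.

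**Figure D2:**
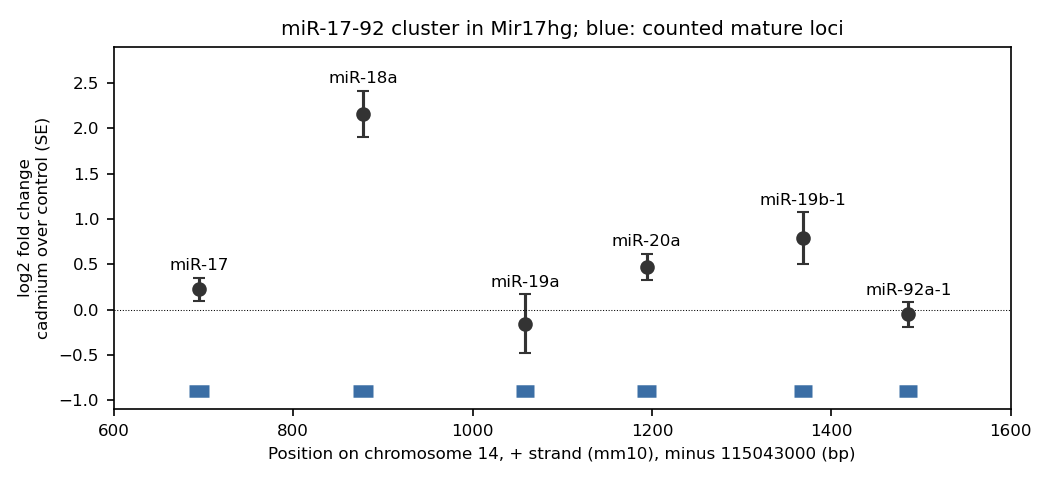
Log2 fold change, cadmium over control, of the tested members of the miR-17-92 cluster against their position on chromosome 14 in bp; points are edgeR estimates with SE (2 libraries per group) and blue bars the counted mature loci. miR-18a lies at 2.16, and the next highest member, miR-19b-1, at 0.79.

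Lists of other tissues and of stress responses were not past the threshold. The medians and camera adjusted p-values were -0.25 and 0.622 for 4 liver loci, -0.22 and 0.322 for 9 kidney and epithelium loci, and 0.06 and 0.895 for 4 muscle loci. miR-148a and miR-192, the most abundant liver members, had -0.41 ± 0.12 and -0.24 ± 0.16. In the kidney and epithelium list 1 locus fell, both over all loci and adjusted over the list alone. This was miR-205, an epithelial miRNA, at -3.05 ± 0.31 from 7.49 ± 1.64 to 0.900 ± 0.224 CPM, while miR-141 had -0.22 ± 0.23. The muscle loci miR-133a-1 and miR-133a-2 share reads at 0.83 ± 0.41, while miR-499 had -0.86 ± 0.52 and miR-208b -0.70 ± 0.69. With 1 locus per sequence the muscle median turned to -0.70. Of 8 inflammation loci, 0 changed (median -0.09, camera adjusted p = 0.867), with miR-21a at -0.03 ± 0.10 and miR-146b at -0.56 ± 0.22. Of 8 p53 and hypoxia loci, 0 changed (median -0.07 but mean 0.12 and test direction up, camera adjusted p = 0.895), with the hypoxia-induced miR-210 at 0.11 ± 0.18, miR-107 at 0.52 ± 0.16 and miR-34a, a p53 target, at -0.40 ± 0.37. Of 7 neural loci, 0 changed (median 0.06 but test direction down, camera adjusted p = 0.944), and miR-128-1 and miR-128-2 stood at -0.01 ± 0.22 and -0.03 ± 0.22. The muscle, liver, inflammation, platelet, and p53 and hypoxia lists also had 0 loci past the threshold adjusted over the list alone, as did the neural list. The let-7 family and the Dlk1-Dio3 cluster had 2 tested loci each, too few for a list test: let-7g 0.14 ± 0.11 and let-7e 0.92 ± 0.33, miR-127 -0.26 ± 0.31 and miR-434 -0.68 ± 0.52, and of these 4 only let-7e passed adjusted over its list alone.

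**Figure D3:**
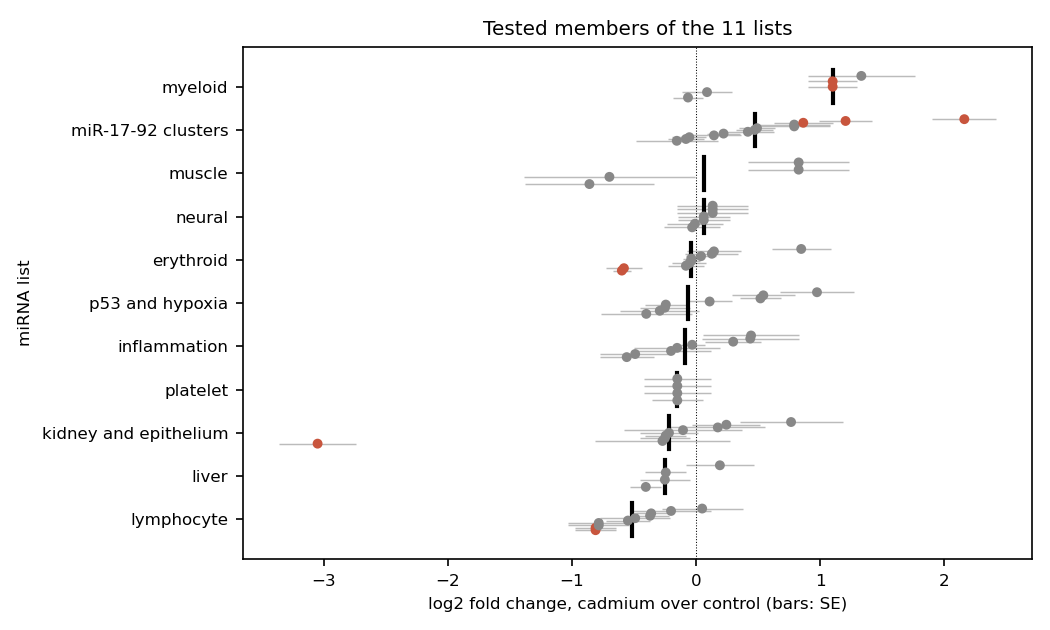
Log2 fold change, cadmium over control, of every tested member of the 11 lists with a list test, by list; points are loci with their SE, red where the edgeR adjusted p is under 0.05, and black bars are list medians. The lymphocyte median lies at -0.52, the miR-17-92 median at 0.47 and the myeloid median at 1.10. Copies with the same reads count separately, and the myeloid median is the value of both miR-24 copies.

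Fragments of ribosomal RNA were lower with cadmium as well. Predicted loci, listed beside the annotated miRNAs, held 0.433% and 0.489% of the counts of annotated and predicted loci in controls 1 and 2, and 0.246% and 0.236% in cadmium libraries 1 and 2. Of 160 predicted loci with 92 distinct sequences, tested together with the annotated ones, 18 fell (11 sequences) and 2 copies of 1 sequence rose. The falls were not confined to annotated rRNA genes. A sequence listed at chromosome 17, 39846725, and at chromosome 6, 3200814, had 9140 and 6674 reads in controls 1 and 2. It had 2080 and 2292 in cadmium libraries 1 and 2 (log2 fold change -1.08 ± 0.19). The source of these falls was not tested. The 11 loci in annotated rRNA genes hold 4 sequences. Of these loci 7 fell, 5 of them copies of the most abundant sequence. That sequence, GGAATACCGGGTGCTGTAGGCTT, counted in the 5S rRNA gene n-R5s2 on chromosome X (6106988 to 6107010, plus strand), had 20371 and 16906 reads in controls 1 and 2 and 3931 and 4205 in cadmium libraries 1 and 2 (log2 fold change -1.43 ± 0.18).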

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

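All tests in this part were chosen after the results were seen, except the 2 on GC content. Loci outside the main test are given here when both cadmium libraries listed them at 2-fold or more the higher control level, with an unlisted control taken as 4 reads. This is an assumption and not a limit, as a locus can be unlisted for reasons other than few reads: miR-3068 had 246 reads in control 1, 78 and 84 with cadmium, and was unlisted in control 2. Loci with the same sequence carry the same reads, so the highest count listed for a sequence was taken. In all, 11 sequences met the rule, 6 of annotated and 5 of predicted loci. The rule takes in rises only, and falls outside the main test exist as well. miR-339 had 592 and 283 reads in controls 1 and 2 and miR-7237 had 33 and 16, and both loci were unlisted in both cadmium libraries. With unlisted loci as 4 reads, their log2 fold changes were -6.04 and -1.91 (edgeR adjusted p = 0.000686 and 0.0411).

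miR-122, the dominant miRNA of hepatocytes (chromosome 18, 65248866 to 65248887, plus strand), had 16 reads in control 1, was unlisted in control 2, and had 102 and 114 reads in cadmium libraries 1 and 2, 12.4-fold above control 1 at the lower cadmium level. The muscle miRNA miR-133b had 8 reads in control 1, was unlisted in control 2, and had 40 and 35 with cadmium, 8.09-fold above control 1; its listed sequence is also the start of that of miR-133a (0.83 ± 0.41). miR-3103 and miR-6975 were unlisted in both controls and stood 8.25-fold and 6.59-fold higher with cadmium on that assumption, on 24 and 25 and on 19 and 25 reads. miR-297c and miR-193a, unlisted in both controls, stood 3.12-fold and 2.77-fold higher on the same assumption, on 9 and 10 and on 8 and 12 reads. Predicted sequences above the controls were one in Gm24105 (unlisted in controls, 16 and 22 reads, 5.55-fold if 4 reads), one listed at 11 positions including chromosome 1, 170945670 (42 and 39 reads against 11 in control 2, 4.68-fold), one at chromosome 19, 38168528 (unlisted in controls, 10 and 21 reads, 3.47-fold if 4 reads), one in Snora3 within Rpl27a (11 and 13 reads against 6 and 7, 2.18-fold) and one listed at 13 positions including chromosome 12, 81561540 (6 and 7 reads against 5 in control 1, 2.08-fold if control 2 had 4).

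The higher miR-122 count, seen against control 1 alone, was set against a liver source. Controls are the deeper libraries, so a difference in depth points the other way and was not tested. RNA released from liver may contribute, as a hypothesis. The 4 tested liver loci had a median log2 fold change of -0.25. Of these, miR-192 and miR-148a already stand at 1487 and 2517 CPM in this blood, a level that would hide a small addition. The locus miR-802 stood at 0.19 ± 0.27, but it is a single locus at 2.51 CPM on 35 to 73 reads. How much miR-802 liver RNA would add beside miR-122 was not measured, so its value cannot decide either. Liver RNA therefore cannot be told apart from a change within blood, and an effect of cadmium on either stays open.

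The lower miR-486 was set against scaling, red cell share and GC content. The log2 ratio of miR-486 to miR-16-1, in which any scaling factor cancels, was 0.99 and 0.87 in the controls and 0.34 and 0.40 with cadmium, a difference of -0.56 ± 0.07, so a shift of all miRNAs alike is not the whole cause. A smaller share of red cell RNA alone would raise markers of other cells alike. The mean change of the myeloid list exceeded that of the lymphocyte list by 1.05 ± 0.37. Without miR-23a, whose counted window is longer in cadmium 2, it did so by 0.81 ± 0.38. These SE are over sequences and not over libraries, and take the sequences as independent. The myeloid loci miR-23a, miR-27a and miR-24-2 lie close together on chromosome 8. Within the myeloid list, miR-142 and miR-27a stood at -0.07 ± 0.12 and 0.09 ± 0.20, so its rise rests on miR-24 and miR-23a. A separate change among white cells would give such a gap too, so the gap cannot exclude a smaller red cell share. Among erythroid loci, miR-144 had -0.58 ± 0.15, close to miR-486, while miR-16-1 had -0.04 ± 0.07. Less the trend with GC content over 211 sequences (0.06 per 10% GC), and with their median change added back, miR-486 stood at -0.68 ± 0.07. The SE is that of the unadjusted change. A change in miR-486 itself, or in the cells that carry it, with cadmium may remain as a hypothesis.

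The higher miR-18a was set against GC content, the cluster transcript and a near-identical miRNA. Less the GC trend, taken in the same way as for miR-486, it stood at 2.20 ± 0.26. More of the whole miR-17-92 transcript would raise its members alike, but miR-18a exceeded the highest other member, miR-19b-1, by 1.37 ± 0.38. Reads of miR-18b, not analysed here, could have been counted as miR-18a. Neighbours in the miR-18b cluster reached a mean of at most 12.1 CPM, against 552 CPM for miR-18a. Of these neighbours miR-106a rose by 1.20 ± 0.22 and miR-20b by 0.86 ± 0.24, while miR-363 stood at 0.14 ± 0.22. Neither their level nor their change measures miR-18b, so this source cannot be told apart. A change in the maturation or stability of miR-18a also stays open and was not tested.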

How the results depend on the processing

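Alternatives are those fixed before the data were examined unless said to be added. None of the 40 loci changed sign under an alternative that tested it, and miR-326, miR-18a and miR-592 stayed past the threshold in each one that tested them. Of the 22 named calls, 9 held under all alternatives that keep every library. Against 40 changed loci (22 higher, 18 lower) and 2 lists, total counts gave 65 (57 and 8), the upper quartile 48 higher and 9 lower, totals without dominant loci 38 higher, a mean CPM of at least 10 gave 26 with 13 higher and only the lymphocyte list among 128 loci tested, and DESeq2 28 lower. Total counts, the upper quartile and totals without dominant loci moved the median of all loci from 0.08 to 0.38, 0.32 and 0.21. With the replicate block there were 19 (10 and 9), all among the 40, and 2 lists; deviations of same-numbered libraries correlate at 0.03, so the numbers give no pairing. Without 1 library, 8 to 122 loci changed, 4 to 66 higher and 4 to 56 lower, with 1 to 3 lists; the lone library of a group is then assumed to vary like the other pair, so these counts follow whichever pair remains. With an estimated correlation 0 lists passed, and with fry 2, lymphocyte and myeloid. Added settings gave 33 loci with identical windows, 29 with 1 locus per sequence, 34 when thinned, 40 and 46 with unlisted loci as 0 and 4 reads (only the lymphocyte list with 4), and 83 (47 and 36) among 436 loci with predicted ones. Causes were not tested except where stated.

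Signs changed for values near 0 that the main test did not call. With total counts these became miR-16-2 and miR-16-1 0.26, miR-22 0.20, miR-92a-1 0.25, miR-92a-2 0.22, miR-142 0.24, miR-126a and miR-199a-1 0.15, miR-192 0.0573, miR-141 0.0780, miR-128-1 0.29, miR-128-2 and miR-21a 0.27, miR-127 0.0426, and the list medians erythroid 0.26, platelet 0.15, liver 0.0529, kidney and epithelium 0.0780, inflammation 0.21, p53 and hypoxia 0.23; of these both miR-16 loci pass the threshold. With the upper quartile they were miR-16-2, miR-16-1, miR-92a-1, miR-21a 0.20, miR-22 0.14, miR-92a-2 and miR-142 0.17, miR-126a 0.10, miR-199a-1 0.11, miR-192 0.00684, miR-128-1 0.25, miR-128-2 0.23, miR-127 0.00519, and the list medians erythroid 0.20, platelet 0.11, liver 0.00311, kidney and epithelium 0.0272, inflammation 0.16, p53 and hypoxia 0.18. Without dominant loci they were miR-16-2 and miR-16-1 0.0878, miR-22 0.0285, miR-92a-1 0.0709, miR-92a-2 0.0434, miR-142 0.0604, miR-128-1 0.12, miR-128-2 0.0935, miR-21a 0.0951, and the list medians erythroid 0.0878, inflammation 0.0336, p53 and hypoxia 0.0580. With predicted loci (added) they were miR-16-2 0.0437, miR-16-1 0.0436, miR-92a-1 0.0314, miR-92a-2 0.00381, miR-142 0.0173, miR-128-1 0.0779, miR-128-2 0.0555, miR-21a 0.0499, and the list medians erythroid 0.0437, p53 and hypoxia 0.0159. Elsewhere miR-27a had -0.00449 with DESeq2 size factors and -0.00455 with DESeq2, and the muscle median was -0.0283 with those factors, -0.76 when summed, -0.00468 with identical windows and -0.70 with 1 locus per sequence. The neural median was -0.0294 with those factors and -0.0135 when summed. The p53 and hypoxia median was 0.0939 with no filter and the inflammation median 0.0926 with identical windows. miR-128-1 had 0.00227 with voom and 0.0159 with the block, and miR-128-2 0.00798 when thinned. Leaving out 1 library gave -0.25 to 0.17 for miR-92a-1, -0.27 to 0.14 for miR-92a-2, -0.34 to 0.0669 for miR-126a, -0.41 to 0.17 for miR-199a-1, -0.26 to 0.29 for miR-128-1, -0.28 to 0.27 for miR-128-2, -0.49 to 0.0638 for miR-127, -0.0272 to 0.0859 for erythroid, -0.41 to 0.17 for platelet, -0.12 to 0.16 for inflammation, -0.0946 to 0.21 for p53 and hypoxia, -0.0984 to 0.30 for miR-27a, -0.48 to 0.0986 for miR-141, -0.0939 to 0.0345 for miR-21a, -0.0234 to 0.23 for miR-210, -0.18 to 0.0424 for miR-142 and -0.0288 to 0.0813 for neural. Of these, miR-27a and both miR-128 loci pass the threshold as higher without control 1, and miR-141 as lower. Without control 2, both miR-92a loci, miR-126a and both miR-128 loci pass as lower. Shares also depend on counting: with every listed locus the erythroid share was 52.3% in controls and 53.2% with cadmium, and that of miR-486 22.8% and 18.5%.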

Other observations

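Members of the same seed family went in different directions in the main test, though with total counts no member of the miR-15 and miR-16 family passed as lower, and with the upper quartile none of the miR-30 family did. The families were looked at only after the test, and miR-15a, miR-497 and the miR-30b, miR-30c and miR-30d loci were chosen after their values were seen. In the miR-15 and miR-16 family, which share a seed and many targets in the cell cycle, miR-15b and miR-195a rose by 1.09 ± 0.13 and 1.06 ± 0.23 on the log2 scale and miR-322 fell by 1.15 ± 0.27. miR-15a stood at 0.04 ± 0.12, miR-497 at -0.42 ± 0.23 and both miR-16 loci at -0.04 ± 0.07. miR-15b and miR-195a rose past the threshold under all 4 other scalings, while miR-322 kept its negative sign under all 4 and lost its call with total counts (-0.85, edgeR adjusted p = 0.0637). miR-15b and miR-16-2 lie in an intron of Smc4, but reads of miR-16-2 cannot be told from those of miR-16-1.

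In the miR-30 family, miR-30a and miR-30e fell by 0.66 ± 0.09 and 0.41 ± 0.11 and miR-30c, counted at 2 loci with the same reads, rose by 0.58 ± 0.11, with edgeR adjusted p-values of 0.00294, 0.0378 and 0.0114. miR-30d had -0.35 ± 0.10 and miR-30b 0.36 ± 0.14, neither past the threshold; miR-30b passed under 3 of the 4 other scalings (0.66 with total counts) and miR-30d with DESeq2 size factors (-0.44). miR-30c rose under all 4 other scalings; miR-30a stayed negative under all 4 and lost its call with the upper quartile (-0.42, adjusted p = 0.0824), and miR-30e lost its call under each of the scalings other than DESeq2 size factors.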
